A study of Mus musculus with 7 samples.

How the data were processed

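RNA of muscle stem cells (satellite cells) from male C57BL/6 mice was measured on 7 Agilent 1-colour arrays labelled with Cy3. The 3 young arrays came from mice aged 2, 2 and 3 months and the 4 geriatric arrays from mice aged 28, 28, 29 and 30 months, per the labels. Cells were sorted from dissociated muscle by flow cytometry for integrin α7 and CD34, against CD31, CD45, CD11b and Sca1, and their RNA was amplified with a protocol for very small cell numbers, per the labels. The titles call the samples biological replicates, and whether each came from 1 mouse or from a pool is not given in the sources used here, so p-values measure the spread between these samples.

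The spot intensity values were quantified with Agilent Feature Extraction 10.7.3.1, per the file headers. In these deposited intensity columns the processed signal had a spatially detrended background subtracted, was detrended multiplicatively within each array, and had surrogate values for spots near background, per the file headers. The mean spot signal and the median local background were raw intensities, and the flags for spots well above background, saturated or outlying were also used, per the file headers. All arrays lay on 1 slide and were scanned on 1 date, so neither could be used as a batch. The authors' value table held values on a log2 scale that were not centred by gene, with a median of 8.02 in every column and nearly the same quantiles in all columns. Its values correlated with log2 mean signal of the same array at r = 0.9995 to 0.9998 across probes, and 1 probe of the array had no value in it. The background correction behind the authors' log2 values stays unknown. The software that made them is not given in the sources used here.

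Main values were log2 of the processed signal minus the array's 75th percentile over probes other than controls. Control spots and outlier spots (124 to 229 per array) were left out, spots of 1 probe were averaged, and no probe was saturated. Of 55681 probes, 41261 were well above background on at least 3 of the 7 arrays and were tested. Each gene was read by its brightest tested probe, the one with the highest mean log2 signal over all 7 arrays, which gave 27393 tested features of 36406 names on the array. They comprised 14196 named genes and 13197 placeholders such as clone names, Gm numbers, accessions and unnamed probes. Names were those of the array design. The reference table of GRCm38.p6 held 26300 of the accessions and lacked 1486 RefSeq accessions, whose names were kept as given. Printed coordinates are those of the array files, on mm9, and the reference table gave the order of genes on chromosome 14 for the segment in the closing section.

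Geriatric replicates 1 and 2 carried the same sample name in their descriptions, although their titles number them separately. Their arrays correlated at r = 0.993 across probes, with a median absolute difference of 0.0879 log2 units. Other pairs of arrays correlated at 0.914 to 0.954, with medians of 0.343 to 0.455. The processed signals of the pair lay within 2 combined errors of each other for 95.8% of probes, against 51.1% to 60.5% for other pairs. Replicate spots within an array had a median SD of 0.0536 to 0.0812 log2 units. No other RNA was hybridised on 2 arrays, so the noise between repeated hybridisations has no second measure here. On the shared name and the combined errors the 2 arrays were averaged and counted as 1 sample, so that 3 young samples were compared with 3 geriatric samples. The plan had counted 4 geriatric samples unless these 2 arrays differed by less than technical noise, which the combined errors were taken to measure, and the permutation test of the first principal component then had 20 labelings of 6 samples in place of those of 7.

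Differences were tested with limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg over all tested features, threshold adjusted p of 0.05) in R 4.3.3 with the data.table package, version 1.17.8. Log2 differences are geriatric minus young. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A probe that was not well above background on any array of a group has only a bound there, and its fold is given as "at least". That fold sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

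The 37 gene lists, 26 of pathways and 11 of cell type markers, were tested with camera (inter-gene correlation 0.01, Benjamini-Hochberg over the lists) where at least 5 members were tested. They were also tested with an estimated correlation and with fry. The pathway lists were satellite cell identity, quiescence, Notch pathway, myogenic commitment and differentiation, CDK inhibitors and RB family, senescence-associated secreted factors, Polycomb repressive complexes, p53 targets, DNA replication and S phase, G2/M and mitosis, immediate early genes, heat shock and chaperones, interferon-stimulated genes, MHC class I antigen presentation, JAK-STAT signalling, NF-kB targets, oxidative phosphorylation, cytosolic ribosomal proteins, autophagy and lysosome, antioxidant and detoxification, DNA damage response and repair, extracellular matrix, TGF-beta and BMP signalling, Wnt signalling, FGF and MAPK signalling, and imprinted genes. The cell type lists were endothelial, macrophage and monocyte, lymphocyte, granulocyte, fibro-adipogenic progenitor, pericyte and smooth muscle, Schwann cell, tenocyte, erythroid, adipocyte and mature myofibre. The value of a list is the median log2 difference over its tested members.

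Genes were named by a rule with 3 parts. The first took up to 12 per direction with the largest difference among genes past the threshold whose groups did not overlap and that were well above background on every array of the brighter group, without placeholders. As fewer passed, up to 6 per direction with the smallest unadjusted p were added and are said not to pass. The second part was Cdkn2a with all its probes, Cdkn2b, Cdkn1a, Pax7, Myf5, Myod1 and Myog. The third was up to 4 members of each described list with the smallest unadjusted p, and any member past the threshold. The lists, this rule, the main test and the other settings listed in advance were chosen before the data were examined.

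The pipeline was tested on simulated data in which 200 of the 27393 features were changed. Called at adjusted p of 0.05 were 4% of those changed by 1 log2 unit, 40% at 2 units, 76% at 4 units and 94% at 6 units (50 features each), with 7 false calls. Of 40 simulated lists of 24 members, the 1 list shifted by 0.6 log2 units passed and 0 of the other 39 did. Simulated features varied independently of each other. In the data the estimated correlation was 0.14 for interferon-stimulated genes and 0.74 for cytosolic ribosomal proteins. The simulation therefore cannot show how many real lists would pass with no group difference. Array signal and the number of arrays limit the precision.

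The other settings listed in advance were normexp background correction with an offset of 50, quantile normalization, scaling by the median, no scaling, the authors' values, no filter on dim probes, probes well above background on all 7 arrays, the mean of a gene's probes, eBayes with trend and robust, array weights, the replicate number as a block, the slide row as a fixed block, slide row 1 alone, other thresholds, other set tests, the 1000 most variable genes for the principal component, and leaving out each array. Counting geriatric replicates 1 and 2 as 2 samples, and leaving out both, were added after the data had been seen. In the slide row fit, duplicateCorrelation gave no estimate from 1 repeated sample, so a moment estimate of the correlation between its 2 arrays (0.865) was used, and lists were ranked on moderated statistics there and in the fits with weights or a trend. Groups of 3 samples are too small for a test of outlying samples, and none was run.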

Results

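Expression was measured in satellite cells, the stem cells of skeletal muscle, sorted from unchallenged muscle of 3 young and 3 geriatric samples after geriatric replicates 1 and 2 were averaged. These 2 arrays shared a sample name, and their processed signals lay within 2 combined measurement errors of each other for 95.8% of probes, against 51.1% to 60.5% for other pairs, so they were counted as 1 sample. Of 55681 probes, 40259, 40424 and 41293 were well above background on young arrays 1 to 3, and 40999, 38893, 38052 and 39129 on geriatric arrays 1 to 4. The 75th percentile of the processed signal was 1330 to 1609 intensity units. Levels below are log2 signal relative to that percentile, with n = 3 samples per group.

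The comparison of geriatric with young cells bears on whether, at very old age, satellite cells leave reversible quiescence for senescence. RNA levels alone cannot settle this. Among named genes, Fam26e and Nell1 rose and Kif23 and Plac9 fell in geriatric cells. Kif23, a kinesin motor of cytokinesis, was well above background on all 3 young arrays and on 0 geriatric arrays. Nell1, a secreted protein with epidermal growth factor-like repeats, was well above background on all 4 geriatric arrays and on 0 young arrays. Cdkn2a, which encodes the cell cycle inhibitors p16INK4a and ARF, was 5.17-fold higher in geriatric cells with no overlap between groups but did not pass the test. Pax7, the transcription factor that marks satellite cells, was at 4.09 ± 0.37 in young and 4.13 ± 0.22 in geriatric cells (SD, n = 3).

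Of 27393 features tested with limma, 7 passed the threshold, 3 higher and 4 lower in geriatric cells. Fam26e (now Calhm5, a member of the calcium homeostasis modulator family; probe at chromosome 10, 33811721 to 33811780 on mm9) was at least 14.1-fold higher (adjusted p = 0.0380). Nell1 (chromosome 7, 58118540 to 58118599) was at least 4.77-fold higher (adjusted p = 0.0267). Kif23 (chromosome 9, 61767492 to 61767732) was at least 10.1-fold lower (adjusted p = 0.0267). Plac9 (listed as Plac9a in the reference; chromosome 14, 26708383 to 26708442), was well above background on every array, at 5.11 ± 0.39 in young and 1.00 ± 0.20 in geriatric cells, and fell by 4.11 on the log2 scale (SE 0.25, adjusted p = 0.0267). The other 3 features had placeholder names, and naming them was decided after their values were seen. Gm16486 rose by 3.61 (SE 0.26, adjusted p = 0.0380), the transcript ENSMUST00000122937 was at least 7.51-fold lower and the unnamed probe A_55_P2239758 at least 9.04-fold lower (adjusted p = 0.0267 for both). The probes of 5 of the 7 features were not well above background on any array of the lower group. Of the 27393 tested features, 214 were not well above background on any array of 1 of the groups.

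With normexp background correction the log2 difference was 2.51 for Fam26e and -4.05 for Plac9 (adjusted p = 0.0165 for both), and Kif23 (-2.26, 0.0512) and Nell1 (1.38, 0.143) no longer passed. With the authors' values it was 2.44 for Fam26e, -2.34 for Kif23 and 1.30 for Nell1. Both sets of differences are smaller than the folds of these 3 genes given above, which therefore hold as bounds for the background-subtracted signal alone. Over the settings in which each was tested the adjusted p was 0.00535 to 0.201 for Fam26e, 0.00535 to 0.175 for Nell1, 0.0142 to 0.147 for Kif23 and 0.00535 to 0.163 for Plac9. The count of 7 was 0 without young replicate 1, young replicate 2 or geriatric replicate 4, where 1622, 2146 and 2114 features had an unadjusted limma p under 0.05, and 2 without young replicate 3 or geriatric replicate 3. With all samples 1980 features had an unadjusted p under 0.05, where 1370 would with no difference, and the groups did not overlap for 12.8% of features, against 10% by chance.

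**Figure D1:**
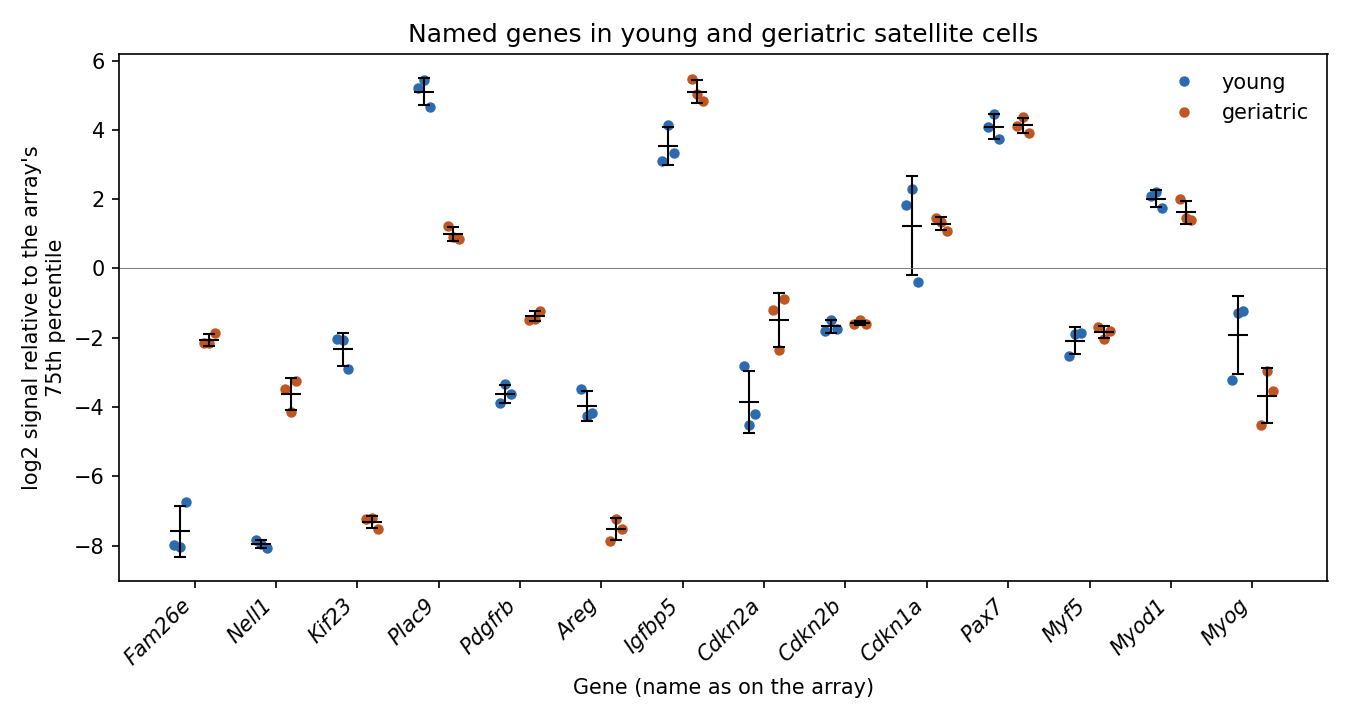
Log2 signal relative to the 75th percentile of each array for 14 named genes; points are samples (geriatric replicates 1 and 2 averaged), blue young and orange geriatric, and bars are mean ± SD of 3 samples. Plac9 lay at 5.11 ± 0.39 in young and 1.00 ± 0.20 in geriatric cells, and Pax7 at 4.09 ± 0.37 and 4.13 ± 0.22.

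Further named genes with the smallest unadjusted p did not pass. On the higher side they were Zmat1 (log2 difference 1.86, adjusted p = 0.0592), Vat1l (at least 12.4-fold, 0.0592), Fn3krp (at least 12.3-fold, 0.0603), Pdgfrb, a platelet-derived growth factor receptor (2.24, 0.0603), Xdh, the xanthine dehydrogenase of purine breakdown (2.43, 0.0764), and Aass, an enzyme of lysine breakdown (1.77, 0.0914). On the lower side they were Areg, which encodes the growth factor amphiregulin (at least 3.25-fold, 0.0592), Dok2, a docking protein of tyrosine kinase signalling (at least 3.34-fold, 0.0592), Adamts17 (-3.23, 0.0851; well above background on 1 geriatric array), Tssk3 (-2.48, 0.0902), Sdk1 (at least 6.48-fold, 0.0914) and Adora2b, an adenosine receptor (-1.93, 0.0959).

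Of the cell cycle inhibitors, Cdkn2a was at -3.85 ± 0.90 in young and -1.48 ± 0.78 in geriatric cells, a log2 difference of 2.37 (SE 0.58, adjusted p = 0.423). Its dimmer probe gave 0.95, with levels of -4.21 ± 0.96 and -3.26 ± 0.21, and there young replicate 2, at -3.11, lay within the geriatric values. Cdkn2b differed by 0.11 (adjusted p = 0.925) and its dimmer probe by 1.05. Cdkn1a, which encodes p21, differed by 0.05 (SE 0.70, adjusted p = 0.992), with young samples at 1.82, 2.28 and -0.40, and by -0.76 without young replicate 3 (adjusted p = 0.745). The dimmest of its 3 probes gave 2.67, with levels of -4.82 ± 0.76 and -2.14 ± 1.31. The CDK inhibitors and RB family list had 10 tested members, 5 of them higher, with a median difference of 0.0044 (-0.23 without young replicate 3) and a camera adjusted p of 0.906. None of its members passed over all genes or adjusted over the list alone.

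Of the myogenic regulators, Myf5 differed by 0.25 (SE 0.25, adjusted p = 0.886; 0.03 without young replicate 1), Myod1 by -0.39 (SE 0.24, adjusted p = 0.803) and Myog by -1.76 (SE 0.67, adjusted p = 0.656). The satellite cell identity list (19 tested, 11 higher, median 0.04) had a camera adjusted p of 0.860. In the list of myogenic commitment and differentiation (16 tested, median -0.02, mean 0.07, adjusted p = 0.954) 0 members passed over all genes, and 4 did adjusted over the list alone. They were Mef2c, a transcription factor of muscle differentiation (at least 3.78-fold higher, well above background on 3 of 4 geriatric arrays), Tmem8c, the fusion protein myomaker (-2.39, likewise 3 of 4), Cdh2, N-cadherin (1.48; its other probe 0.35), and Myf6 (1.31). The quiescence list (17 tested, 9 higher, median 0.04, adjusted p = 0.860) held 1 such member, Angpt1, a ligand of the Tie2 receptor (2.53).

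The lists that bear on cell division and senescence did not pass in the main camera test. Senescence-associated secreted factors had 19 tested members, 14 of them higher, a median of 0.34 and a camera adjusted p of 0.233. Over all genes 0 of its members passed. Adjusted over the list alone, 2 passed in opposite directions, Areg lower (at least 3.25-fold) and Igfbp5, an insulin-like growth factor binding protein, higher (1.58, from 3.52 ± 0.55 to 5.11 ± 0.34). The cytokine Il6 differed by 2.54 (SE 1.11, adjusted p = 0.702) and was well above background on 1 young and 3 geriatric arrays. DNA replication and S phase (26 tested, 16 lower) had a median of -0.20 and an adjusted p of 0.158. Its sample medians were 0.07, -0.06 and 0.38 in young and 0.02, -0.30 and -0.19 in geriatric cells, and its median was -0.07 without young replicate 3, -0.09 without geriatric replicate 3 and -0.03 without geriatric replicate 4. With the slide row as a block it was -0.12, and within row 1 -0.05. G2/M and mitosis (18 tested, 12 lower) had a median of -0.26 and an adjusted p of 0.249, with Mki67 at -1.05 (-0.63 without young replicate 3; its dimmer probe at -3.81) and Plk1 at 1.02. Its sample medians were 0.15, 0.0012 and 0.53 in young and 0.05, -0.12 and -0.44 in geriatric cells, and its median was -0.09 without geriatric replicate 4 and -0.55 without young replicate 2. With the slide row as a block it was -0.26, and within row 1 -0.0040. With the mean of a gene's probes in place of the brightest probe the list passed (-0.52, adjusted p = 0.0177). The p53 targets (25 tested, median 0.08, mean 0.09, adjusted p = 0.860) leaned lower in the camera test while 14 were higher and 11 lower. DNA damage response and repair had a median of -0.17 (0.158) and Polycomb repressive complexes -0.05 (0.671). The former was -0.03 without young replicate 1 and -0.23 without young replicate 2. The latter was 0.0092 without geriatric replicate 4 and -0.13 without young replicate 1.

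Interferon-stimulated genes rose as a list with camera at a fixed correlation, though not with an estimated one (adjusted p = 0.719). Of 24 tested members 20 were higher in geriatric cells, the median difference was 0.55 and the camera adjusted p was 2.96e-04. The members deviated from their own means by a median of -0.26, 0.05 and -0.47 in the young samples and 0.15, 0.42 and 0.24 in the geriatric samples. Examples were Ifit1 (1.17, SE 0.37), Xaf1 (0.58, SE 0.19), Cxcl10 (2.27, SE 0.95) and Dhx58, a sensor of viral RNA (0.96, SE 0.41), none of which passed alone. Without young replicate 3 Ifit1 was at 0.76, Cxcl10 at 1.41 and Dhx58 at 0.64. MHC class I antigen presentation rose too, with 12 of 16 members higher, a median of 0.35 and an adjusted p of 0.0167 (adjusted p = 0.870 with an estimated correlation); the sample medians were -0.04, 0.17 and -0.39 in young and 0.18, 0.22 and -0.0032 in geriatric cells. Its leading members were Psmb8 (1.08), Tap2 (0.66), Nlrc5 (0.63; its other probe 1.91) and Tap1 (1.05), which serve peptide processing, peptide transport and transcription of the class I genes. Tap2 was at 0.42 without young replicate 1, Nlrc5 at 0.37 without young replicate 2 and Tap1 at 0.62 without geriatric replicate 3. The MHC class I list did not pass without young replicate 3 (median 0.20, adjusted p = 0.417) or geriatric replicate 3 (0.131), and the interferon list passed without each array in turn (adjusted p 4.94e-06 to 0.00652).

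The Wnt signalling list rose, with 14 of 17 tested members higher, a median of 0.36 and a camera adjusted p of 0.00949 (adjusted p = 0.719 with an estimated correlation). It mixes ligands and receptors with antagonists, so its median does not measure the activity of the pathway. Without geriatric replicate 4 the median was 0.62. The median deviations were -0.29, -0.10 and -0.24 in the young samples, 0.60 in the averaged geriatric sample, 0.26 in geriatric replicate 3 and -0.19 in geriatric replicate 4. The leading members were Sfrp5, a secreted Wnt antagonist (1.62, SE 0.36), the receptors Fzd4 (1.11, SE 0.30) and Fzd7 (0.81, SE 0.39; 0.52 without the averaged geriatric sample), and Lgr4, the receptor of R-spondins (0.79, SE 0.32). Imprinted genes rose, with 19 of 24 higher, a median of 0.26 and an adjusted p of 0.0167 (adjusted p = 0.719 with an estimated correlation). The sample medians were -0.29, 0.12 and -0.27 in young and 0.21, 0.10 and 0.06 in geriatric cells. The list's median was 0.17 without young replicate 1, 0.41 without young replicate 2 and 0.16 without the averaged geriatric sample. Among them were Ndn, a growth suppressor (1.20, SE 0.24), the growth factor gene Igf2 (0.88, SE 0.25), the proteoglycan gene Dcn (1.56, SE 0.58) and Usp29 (2.76, SE 1.04, well above background on 2 of 3 young arrays). Cytosolic ribosomal proteins fell by a median of 0.08, with 67 of 78 lower and an adjusted p of 0.0354 (adjusted p = 0.963 with an estimated correlation). The sample medians were 0.08, 0.05 and -0.04 in young and -0.18, -0.07 and 0.16 in geriatric cells. The list's median was -0.17 without geriatric replicate 4, -0.04 without geriatric replicate 3, -0.05 without either young replicate 1 or geriatric replicate 1, and -0.00044 without the averaged geriatric sample. Rpl21 was at -0.93 (SE 0.21; its other probe -0.04). Without geriatric replicate 3 the adjusted p was 0.0797 for Wnt signalling, 0.0797 for imprinted genes and 0.299 for ribosomal proteins. Imprinted genes also did not pass without young replicate 1 (0.163) or young replicate 3 (0.0835), nor ribosomal proteins without young replicate 1 (0.197), young replicate 2 (0.109) or geriatric replicate 1 (0.123).

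Of the markers of other cell types that muscle holds, those of fibro-adipogenic progenitors, the stromal cells between myofibres, rose. Of 11 tested, 10 were higher, with a median of 0.73 and a camera adjusted p of 0.00949 (adjusted p = 0.719 with an estimated correlation). The list did not pass without young replicate 1 (0.0503) or geriatric replicate 3 (0.0946), and its median was 0.41 without geriatric replicate 4. Its members deviated from their own means by a median of -0.33, -0.23 and -0.24 in the young samples, -0.05 in the averaged geriatric sample, and 0.60 and 0.49 in geriatric replicates 3 and 4. Dpt passed adjusted over the list alone (0.75, SE 0.17), and Dcn (1.56), Mfap5 (2.45) and Smoc2 (1.10) had the next smallest p. Mfap5 was at 1.39 without young replicate 3 and Smoc2 at 0.54 without geriatric replicate 3. Of the 11 markers, 10 were well above background on every young array, and 2, Dcn of the imprinted list and Col1a1 of the extracellular matrix list, belong to another list as well. Ly6a, the gene of the Sca1 antigen used to exclude cells in the sort, differed by 1.22 (SE 1.22, adjusted p = 0.890) and was well above background on 2 young and 2 geriatric arrays. Its levels were -5.09, -6.65 and -4.06 in young cells, -6.52 on both arrays of the averaged geriatric sample, and -3.16 and -2.47 in geriatric replicates 3 and 4.

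Markers of the other cell types did not pass as lists in the main camera test. Endothelial markers had a median of 0.07 (camera adjusted p = 0.860), with sample medians of 0.05, -0.00096 and 0.18 in young cells, -0.17 in the averaged geriatric sample, -0.57 in geriatric replicate 3 and 1.67 in geriatric replicate 4. The list's median was -0.63 without geriatric replicate 4 and 0.44 without geriatric replicate 3. Macrophage and monocyte markers had a median of 0.23 (0.158), with sample medians of -0.04, -0.29 and -0.18 in young cells, -0.10 in the averaged geriatric sample, and 0.34 and 0.49 in geriatric replicates 3 and 4. The median was 0.18 for lymphocyte markers (0.681), 0.16 for pericyte and smooth muscle markers (0.195) and 0.21 for adipocyte markers (0.115). For lymphocyte markers it was 0.08 without young replicate 1 and 0.32 without the averaged geriatric sample. For pericyte and smooth muscle markers it was -0.0089 without young replicate 3 and 0.24 without young replicate 1. Schwann cell markers had a median of 0.04 and a mean of -0.16 (0.860), tenocyte markers -0.25 (0.860), erythroid markers 0.30 (0.598), and mature myofibre markers a median of 0.14 and a mean of -0.02 (0.954). The granulocyte list had 3 tested members, a median of -0.13 and no set test. Single members that passed adjusted over the list alone were Cd79a (1.27; its other probe -0.08) among lymphocyte markers, Pdgfrb among pericyte markers, Cfd (1.71) among adipocyte markers, and Thbs4 (1.87) and Chad (-1.10, well above background on 3 of 4 geriatric arrays) among tenocyte markers. Over all genes 0 members of these lists passed.

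The extracellular matrix list did not pass (27 tested, 14 higher, median 0.05, mean 0.36, camera adjusted p = 0.671). Its members moved both ways, and 0 of them passed over all genes. Adjusted over this list alone, which takes no account of the other lists, 6 passed. The metalloproteinase inhibitor Timp3 (2.57), the collagen cross-linking enzyme Lox (2.10; its other probe 0.91), the laminin chain Lama4 (2.03) and Col15a1 (1.20) were higher, and elastin, Eln (-1.58), and Lamb1 (-1.09) were lower. JAK-STAT signalling (13 of 19 higher, median 0.19, camera adjusted p = 0.102) was led by Osmr, the oncostatin M receptor (1.99, SE 0.49). This list's median was 0.11 without young replicate 3, 0.28 without young replicate 1 and 0.06 with the slide row as a block. NF-kB targets had a median of 0.21 (camera adjusted p = 0.184). Immediate early genes, of which 22 of 28 were higher, had a median of 0.14 (0.184), and oxidative phosphorylation genes, of which 55 of 84 were lower, had a median of -0.05 (0.115). The immediate early median was -0.03 without young replicate 3 and 0.25 without young replicate 2. The oxidative phosphorylation median was -0.02 without geriatric replicate 3 and -0.10 without the averaged geriatric sample.

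The remaining lists did not pass either. Their medians were 0.03 for the Notch pathway (camera adjusted p = 0.954), -0.0045 for heat shock and chaperones (mean 0.09, 0.954), 0.03 for autophagy and lysosome (mean -0.02, 0.954), 0.01 for antioxidant and detoxification (0.809), 0.07 for TGF-beta and BMP signalling (0.671) and -0.02 for FGF and MAPK signalling (mean 0.11, 0.906).

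**Figure D2:**
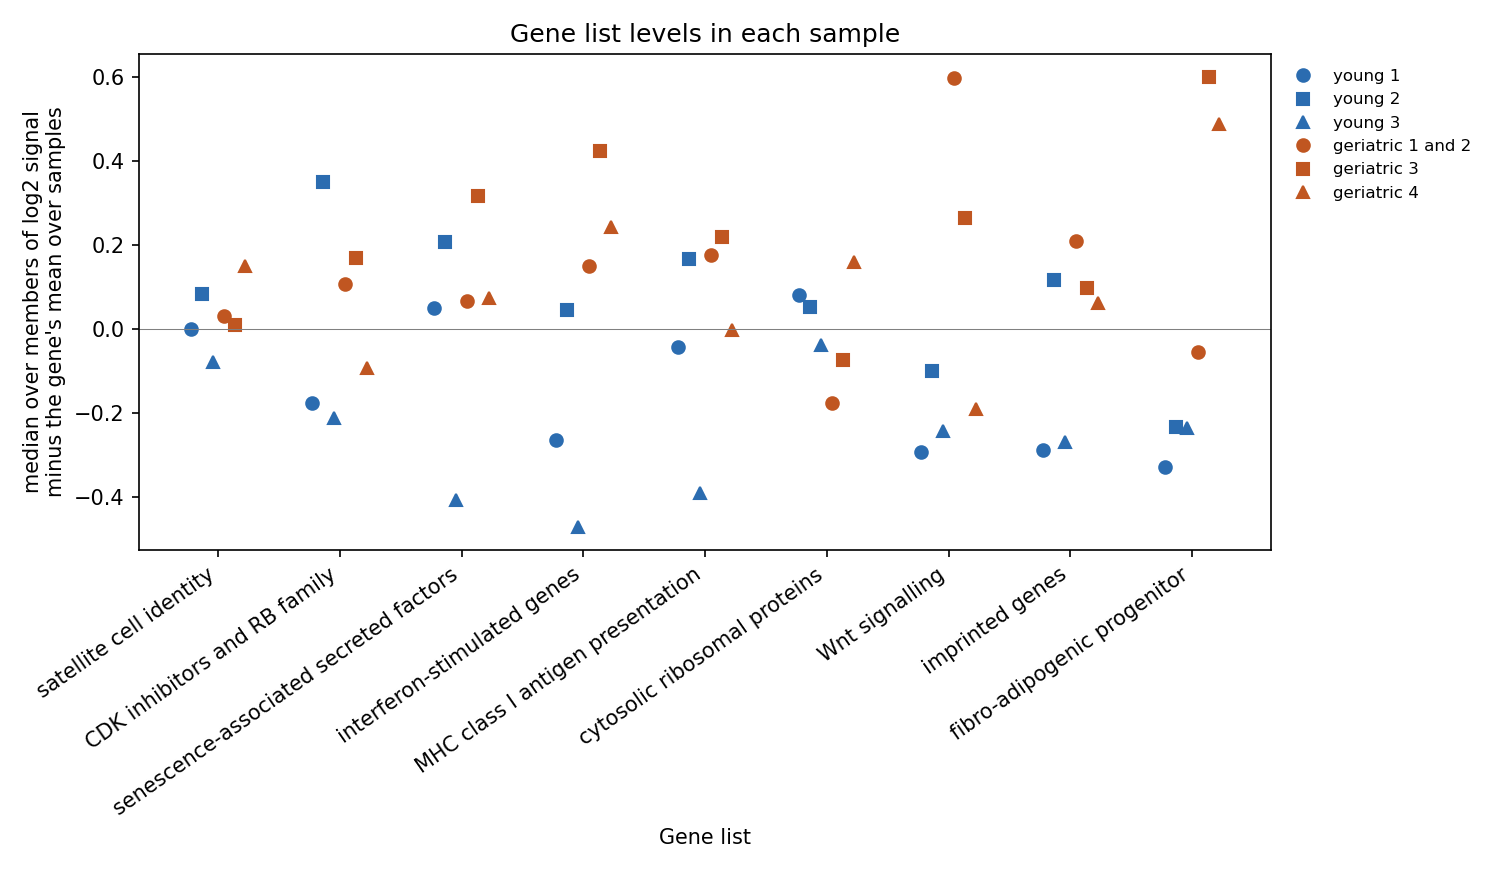
Median over the tested members of 9 gene lists of log2 signal minus the member's mean over samples, for each sample (blue young, orange geriatric; marker shapes tell the samples of a group apart; geriatric replicates 1 and 2 averaged). For fibro-adipogenic progenitor markers geriatric replicates 3 and 4 lay at 0.60 and 0.49 and the averaged geriatric sample at -0.05.

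Across the lists, 6 of 36 passed with camera, 5 higher and 1 lower, and 0 with an estimated correlation or with fry, where the smallest adjusted p was 0.719 and 0.320. At an unadjusted p under 0.05 there were 10, 0 and 3 lists. Fry's test for change in either direction passed 9 lists, and the 6 were not among them. Of pathways these were senescence-associated secreted factors (adjusted p = 0.00390), extracellular matrix (0.00454), myogenic commitment and differentiation (0.00513), JAK-STAT signalling (0.00969) and NF-kB targets (0.0417). Of cell types they were markers of pericytes and smooth muscle (0.00126), adipocytes (0.00225), tenocytes (0.0190) and lymphocytes (0.0417). A pass in this test does not show a list moving as a set. The pericyte, adipocyte and lymphocyte lists each held 1 member at an unadjusted limma p under 0.05. Senescence-associated secreted factors held 2 higher and 1 lower. The first principal component held 28.8% of the variance and placed the young samples at -46.9, -23.9 and -63.1 and the geriatric samples at 106, 30.8 and -2.87. An exact permutation test of the group means, 2-sided, gave p = 0.1, the smallest that 3 against 3 samples allow.

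The young arrays and geriatric array 1 lay in row 1 of the slide and geriatric arrays 2 to 4 in row 2. With the row as a fixed block, 6 features passed, 5 of them among the 7, and within row 1 alone 3 passed, 0 of them among the 7. Row 1 holds 1 geriatric array, which is assumed there to vary like the young arrays, so that its p-values say little. Log2 differences with the block and within row 1 were -4.13 and -3.91 for Plac9 and 2.47 and 2.70 for Cdkn2a. With the block the adjusted p was 0.0579 for Fam26e and 0.0463 for Nell1, Kif23 and Plac9, and within row 1 it was 0.201, 0.0980, 0.144 and 0.163. All 6 lists passed with the block and 4 of them within row 1, under that assumption about 1 array. Medians with the block and within row 1 were 0.62 and 0.45 for interferon-stimulated genes, 0.32 and 0.35 for MHC class I (adjusted p = 0.105 within row 1), 0.42 and 0.82 for Wnt signalling, 0.31 and 0.39 for imprinted genes, -0.20 and -0.27 for ribosomal proteins, and 0.61 and 0.16 for fibro-adipogenic progenitor markers (adjusted p = 0.760 within row 1).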

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

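Counting geriatric replicates 1 and 2 as 2 samples and leaving out both were chosen after the data were seen; the other settings were fixed in advance. No result reversed past the threshold. The count of 7 genes was 4 (3 of the 7 kept) with normexp background correction, 4 (3 kept) with the authors' values and 1 with trend and robust. It was 38 at an adjusted p of 0.1, 64 (39 higher, 25 lower) with geriatric replicates 1 and 2 as 2 samples, and 1 without both. With probes well above background on all 7 arrays it was 2, both of them among the 7. That filter removes the other 5 whatever their difference, as they were not well above background on any array of the lower group. With trend and robust the feature that passed was Plac9 (limma adjusted p = 0.00936), which was well above background on every array. With normexp and with the authors' values Kif23 and Nell1, dim in the lower group, shrank and no longer passed. Fam26e, likewise dim in the lower group, also shrank but passed. Why normexp, the authors' values and the trend model gave fewer was not tested. Without scaling, 5 were higher and 4 lower, with quantile normalization 3 and 5, and without a filter on dim probes 1 and 4. Leaving out each array gave 0 to 8 genes, with 0 without young replicate 1, young replicate 2 or geriatric replicate 4.

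The 6 lists were 0 with an estimated correlation and 0 with fry, 1 to 8 when each array was left out, 3 without young replicate 1 and 1 without geriatric replicate 3, and 4 to 8 in the other settings. Without both arrays of the averaged geriatric sample the adjusted p was 0.0820 for MHC class I, 0.0933 for Wnt signalling, 0.0820 for imprinted genes and 0.686 for ribosomal proteins. Without a filter it was 0.126 for MHC class I and 0.169 for imprinted genes, and with quantile normalization 0.150 for ribosomal proteins (0.155 with the authors' values). The permutation p of the first principal component was 0.1 to 0.2 when each array was left out.

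The replicate number as a replicate block gave 0 genes with limma, against 3553 at an unadjusted p under 0.05. It gave 5 lists, without fibro-adipogenic progenitor markers (adjusted p = 0.0822). This fit counted the arrays of the averaged geriatric sample as separate samples in separate blocks, as if their RNA were independent. Its counts and p-values therefore cannot be set beside those of the main test. Deviations of young and geriatric arrays of the same number correlated at -0.05, 0.07 and -0.0045, and not every sample correlated best with its own number, so the numbers were not taken as pairs. Over 165 named genes, 3542 of 3599 recomputed values kept direction and side of the threshold, 39 no longer passed and 18 came to pass. Over 36 lists it was 809 of 861, with 35 and 17. Signs changed in 28 and 70 cases in which neither value passed, and these are counted as kept. A slide or scan date block was not run, as there was 1 of each. Low signal limits the folds of 5 of the 7 genes to bounds.

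Lists that did not pass came to pass in 17 cases. With the authors' values they were immediate early genes (adjusted p = 0.0488), JAK-STAT signalling (0.0338) and NF-kB targets (0.0374), and without young replicate 2 immediate early genes (0.0193), NF-kB targets (0.0160) and DNA damage response and repair (0.0160). Without both arrays of the averaged geriatric sample they were DNA replication and S phase (median -0.36, 0.0416), oxidative phosphorylation (0.0179) and macrophage and monocyte markers (0.00219). The trend model passed JAK-STAT signalling and oxidative phosphorylation (both 0.0403), and JAK-STAT signalling also passed without geriatric replicate 4 (0.0445). Oxidative phosphorylation passed with median scaling (0.0233), without scaling (0.0365) and without a filter (0.0207), pericyte markers with probes well above background on all 7 arrays (0.0333), and G2/M and mitosis with the mean of a gene's probes (0.0177). With the replicate block, which counts the arrays of the averaged geriatric sample separately, the median was 0.0080 for DNA replication and S phase. For G2/M and mitosis it was -0.13 there. Without young replicate 3 the medians of 9 lists that had not passed turned sign, the largest moves being those of tenocyte markers (from -0.25 to 0.15) and CDK inhibitors and the RB family (from 0.0044 to -0.23), and NF-kB targets were then at 0.04. Such turns numbered 8 without the averaged geriatric sample, 7 without geriatric replicate 4 and 6 without young replicate 1. Without each other array they numbered 2 to 4. Endothelial markers moved from 0.07 to -0.63 without geriatric replicate 4. The cause was not tested.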

Other observations

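The tests of the slide row, of immune cells, of young replicate 3 and of stromal transcripts were chosen only after the results were seen, and for the slide row a comparison within row 1 was run before the comparison of the RNA hybridised in both rows. For immune cells 19 markers were used first, without Cd74, H2-Aa and H2-Ab1, which interferon also induces (median -0.0028); all the tested ones are used below. The splits of the samples, the segment test and the substrain test were fixed before their values were seen.

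Stress and signalling genes of the lists showed further differences, none of which passed over all genes. The metallothioneins Mt1 and Mt2 differed by 0.84 (SE 0.25) and 0.54 (SE 0.20), Gclm, an enzyme of glutathione synthesis, by -0.59 (SE 0.19), and Hmox1, which degrades heme, by 1.05 (SE 0.37; 0.65 without young replicate 1; its other probe by 0.04). Klf2 differed by 1.32 (SE 0.43), Perp, a p53 target, by 4.26 (SE 1.18, well above background on 2 of 3 young arrays), the Notch ligand gene Jag1 by 1.19 (SE 0.46) and the growth factor gene Fgf1 by 1.72 (SE 0.50; its other probe by 0.18). Of replication genes, Cdc6, which loads the replicative helicase, was at least 1.67-fold lower and Uhrf1, which maintains DNA methylation, differed by -1.74 (SE 0.50). Smad3, a mediator of TGF-beta signals, differed by -0.56 (SE 0.16) and Plk2 by -1.18 (SE 0.36).

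The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. For genes past the threshold 1 of the 10 splits, the real one, gave as many as 7, and the highest other gave 2. For gene lists 3 of the 10 splits gave 6 or more, and the highest other gave 11, reached both by young 1, young 3 and the averaged geriatric sample against the rest and by young 1, young 3 and geriatric 4 against the rest.

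Plac9 and D14Ertd449e (now Tmem254a), a gene of the same part of chromosome 14 that was chosen after its values were seen, were both lower in geriatric cells, by log2 differences of -4.11 and -3.06 (adjusted p = 0.0851). The slide row as the whole cause is argued against, because the RNA hybridised in both rows (geriatric replicates 1 and 2) differed between them by 0.144 log2 units or less for both genes, and Plac9 stayed at -4.13 with the row as a block. A difference at 1 genomic segment between the mice is a candidate explanation: the other 2 tested genes among the 14 there in the reference, Duxbl (-2.91, adjusted p = 0.701) and Gm10394 (-2.12, adjusted p = 0.531), had a median of -2.51 (-1.53 without geriatric replicate 3), against a median size of 0.214 for the 20 tested genes around the segment. Gm3002, left out in advance because its fall had been seen and placed outside the segment by the reference, differed by -1.98 (its other probe by -0.36); whether these genes' probes share signal was not tested, and age-related regulation of these genes stays open as untested. Different C57BL/6 substrains stay open too, since Nnt, a gene lost in 1 of them, differed by 0.72 (SE 0.23), between the values that either case would need.

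Interferon-stimulated and MHC class I genes, 40 in both lists, had a median difference of 0.51 (95% bootstrap interval over genes 0.30 to 0.63). The slide row as the whole cause is argued against by the RNA hybridised in both rows, which differed between them by a median of 0.0146 (-0.01 to 0.02), and within row 1 geriatric array 1 exceeded the young mean by a median of 0.42 (0.15 to 0.63). Young replicate 3, the lowest sample in both lists, is argued against as the sole source among these samples. Without it the median was 0.31 (0.17 to 0.57), although the MHC class I list alone then no longer passed. The intervals here are over genes, which may vary together, and do not measure the spread between samples. Immune cells among the sorted cells stay undecided, although the sort excluded CD45 and CD11b. The CD45 gene Ptprc was at -2.96 in young and -2.58 in geriatric cells, and the CD11b gene Itgam at 6.54 and 6.61. The other tested macrophage and monocyte markers were dimmer in young cells, Csf1r at 2.11 and the rest from -6.80 (H2-Aa) to -2.44 (Fcer1g). Of the granulocyte markers, Csf3r was at 6.33, Camp at -3.42 and Mpo at -5.20. The Itgam level alone therefore does not measure the share of immune cells, and why it was high was not tested. The 12 tested macrophage and monocyte markers, 8 higher and 4 lower, had a median of 0.23 (-0.16 to 1.19). Without the averaged geriatric sample it was 0.52 (camera adjusted p = 0.00219). Cd74 (1.57), H2-Ab1 (1.74) and Cd14 (0.81) were higher, and Cd68 (-0.53), Fcer1g (-0.40) and Fcgr3 (-0.31) lower. H2-Ab1 was well above background on 1 young and 2 geriatric arrays. The 22 markers of macrophages, lymphocytes and granulocytes together had a median of 0.04 (-0.16 to 0.40), with Cd79a at 1.27 (its other probe -0.08). An effect of age on both lists stays open as untested, and so do other differences between the mice.

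Fibro-adipogenic progenitor markers were higher mainly in geriatric replicates 3 and 4, where macrophage and monocyte markers had sample medians of 0.34 and 0.49 and endothelial markers -0.57 and 1.67, and stromal cells among the sorted cells may account for it. Pdgfra, a stromal receptor gene also chosen to test this, was not among the tested features and has no value here. The test of 5 stromal transcripts decides nothing, since Col1a1 (-0.01), Gsn (0.02) and Clec3b (0.05) belong to the list itself and Col1a2 (1.12) and Col3a1 (-0.13) went both ways, for a median of 0.0192 (95% bootstrap interval -0.13 to 1.12). The sort excluded cells with Sca1, which would remove such cells, yet the Sca1 gene Ly6a, a member of the list, was higher in geriatric replicates 3 and 4 (-3.16 and -2.47) than in the young samples (-6.65 to -4.06), and 10 of the 11 markers were well above background on every young array. The slide row as the whole cause is argued against, although both replicates lay in row 2, because the RNA hybridised in both rows differed over the 11 genes by a median of 0.0287 (-0.11 to 0.11); within row 1 geriatric array 1 exceeded the young mean by 0.157 (-0.10 to 0.61). An age-related rise of these transcripts within satellite cells stays open as untested.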
